A study of Mus musculus with 17 samples.

How the data were processed

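RNA of single cells was measured with 10x Genomics droplet kits in 9 libraries of mouse testis. Cells of 8 libraries were sorted by flow cytometry for c-KIT and read with a 5' kit (4 iKO and 4 control), and 1 adult wild-type library was read with a 3' kit (version 2 chemistry), per the labels. The deposited values are raw UMI counts per gene and barcode, with empty droplets still in the matrices. Per the submitters' processing notes the tools were Cell Ranger 2.0.0 and 6.0 and Seurat, and the build was mm10. The matrix headers of the 5' libraries name version 4 of Cell Ranger. Which steps Seurat was used for and whether counting used strand are not given in the sources used here. Gene coordinates come from GENCODE release M21 on GRCm38, the same assembly as mm10. Of 31053 genes in the 5' matrices, 30934 identifiers were in that annotation and 30468 had the same symbol, and the adult matrix listed 27998 genes.

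A barcode was kept as a cell with at least 2000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Doublets were scored by simulated pairs of cells, and the highest-scoring barcodes were removed at 0.8% per 1000 cells, which took 356 of 18213 barcodes (1.95%) in the c-KIT libraries and 46 of 2406 in the adult library. This fixes the number removed, so it is an assumed rate and not a measured one. Counts were scaled to 10000 per cell and logged. The 2000 most variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1.0 gave the clusters, with no batch correction. Cbx2, mitochondrial and ribosomal protein genes were kept out of the variable genes. In the c-KIT libraries no Polycomb gene of the fixed lists was among them.

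Clusters were named only from marker lists fixed before the data were examined, by the mean log2 level of a list's detected markers relative to the other clusters. A name needed at least 3 detected markers. A cluster whose first gene was less than 2-fold above the other cells, whose leading genes held more markers of another class, or that carried germ cell and somatic or spermatid markers together stayed unnamed. The scoring limit and the rule on mixed clusters were set after seeing the clusters and before any comparison of groups. For the adult library a share limit in the mixed rule, the use of elongating spermatid markers in it and a second clustering of mixed clusters were set after seeing its clusters. So was a limit on the free-RNA share above which nothing was subtracted. Unnamed clusters held 503, 965, 191 and 194 cells in control replicates 1 to 4 and 598, 828, 186 and 124 in iKO replicates 1 to 4. Names may differ from those the study gave.

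Cells are not replicates, so UMI counts were summed per library and class, with at least 20 cells of the class per library. The sums were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr, no block) under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM of named genes are TMM-scaled, while Cbx2 per library is given in plain CPM. Class shares were compared by a two-sided exact permutation test over all 70 assignments of the libraries, with Benjamini-Hochberg adjustment over the classes. Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with the estimated correlation and fry beside it, and Cbx2 was left out of its own list. With the estimated correlation, and by the directional test of fry, no list passed in any class. By the mixed test of fry, which takes changes in either direction, no list passed without the block, and with it 1 did, the pachytene markers in undifferentiated cells (adjusted p = 0.0297). Without the block no list member passed over all genes. With it some did, among them Meioc and mt-Atp8 in differentiating cells and mt-Nd3 in undifferentiated cells. Effects in different classes were compared by a class by group term, which called 0 genes in edgeR for each pair of classes, with 436, 98 and 120 genes at an unadjusted p under 0.05. Each is fewer than chance alone would give among the 13265, 13849 and 11096 genes tested. The 0 is therefore little evidence that effects were alike.

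The fixed lists were canonical PRC1, variant PRC1, PRC2, Hox genes, developmental regulators often bound by Polycomb, CDK inhibitors, p53 targets, the retinoic acid pathway, G1/S and replication, and G2/M and mitosis. They also held DNA methylation, the piRNA pathway, immediate early and heat shock genes, interferon response, apoptosis, KIT signalling and its readouts, mitochondrially encoded genes, cytosolic ribosomal proteins and the cell type markers. A list needed 3 tested members, which left 28 lists in differentiating, 25 in undifferentiated, 25 in early meiotic and 31 in all germ cells. Mast cell and erythroid markers had too few tested members in every class.

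Named genes followed a rule fixed in advance. Cbx2 came first, then up to 10 genes per direction with the largest log2 difference past the threshold, at least 10 CPM and every iKO library on the same side. Of each list, at most 4 members past the threshold were named, or at most 2 with the smallest p as values. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were given as values, with Y-linked and unnamed gene models replaced. For the adult library the rule took Cbx2 and the Polycomb lists.

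Same-numbered libraries deviated together, which was decided before the fits were compared. Their correlations of deviations from the group means over genes were 0.691 to 0.793 in differentiating, 0.167 to 0.293 in undifferentiated, 0.345 to 0.824 in early meiotic and 0.957 to 0.988 in all germ cells. Not every library correlated best with its own number. The highest correlation with another number was 0.713 against 0.691 for iKO replicate 4 in differentiating cells, 0.258 against 0.251 for control replicate 3 in undifferentiated cells and 0.591 against 0.345 for iKO replicate 1 in early meiotic cells. The group means covered both protocol sets, which were sorted to different concentrations, so libraries of the same set can correlate whatever their number. In all germ cells the highest correlation with another number was 0.912 to 0.968, below the same-number value in every pair but close to it. These correlations thus hold the set as well as the number. The pairing comes from the data, since the labels give shared numbers only. A fit with the replicate number as a block is therefore given beside results it changes, such as the 10 genes in differentiating cells. No pair of replicates agreed within the counting noise of UMIs, with chi-square per degree of freedom of at least 8.07. That noise leaves out the draw of cells, so the values cannot tell separate samples from aliquots of the same sample.

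Each count test was tried on simulated counts with 200 genes changed, besides a list changed 1.25-fold whose members are among the calls. The counts were drawn from the means of each protocol set and the spread of the real libraries. They held no effect of the replicate number, so the rates of the blocked fit need not hold for the real counts. Without a block it recovered 52.2%, 73.1% and 87.9% of genes changed 1.5-fold, 2-fold and 4-fold in differentiating cells, with 0 false calls. In undifferentiated cells it recovered 41.8%, 83.6% and 93.9%, in early meiotic cells 13.4%, 44.8% and 80.3%, and in all germ cells 25.4%, 59.7% and 75.8%, with 1, 0 and 0 false calls. With the block more was recovered, 77.6%, 92.5% and 95.5% in differentiating cells, but 28 of 221 calls were false, which is above the nominal rate. The block also gave 9 false of 180 calls in undifferentiated, 15 of 201 in early meiotic and 20 of 180 in all germ cells. The class by group term recovered 82% of 200 genes changed 2-fold, with 16 false calls. Both simulated classes were drawn from differentiating counts. The real sums of undifferentiated and early meiotic cells are smaller, so this rate need not hold for them. A list changed 1.25-fold passed camera in every class and an unchanged list in none. Genes were drawn independently of each other, so this does not show how often camera calls lists whose members vary together, as in real counts.

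Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, the replicate block, the protocol set as a covariate, leaving out each library, keeping doublets, a stricter cell filter (1000 genes and 5% mitochondrial UMIs), centring genes within libraries before clustering, and resolutions 0.5 and 1.5. Others were chosen after seeing the data: each protocol set alone, the block with pairs left out or with another cell filter, another rule for calling cells, other class limits or denominators, and comparisons of classes within the controls. Adult levels carry 95% exact Poisson intervals and shares exact binomial ones, with a floor of 3 counts, and adult cells were also thinned to 2000 UMIs. Free RNA was profiled in barcodes with at most 50 UMIs. Clustering and figures used Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.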

Results

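Single-cell RNA was profiled in 9 libraries of mouse testis (strain C57BL/6J). Of these, 8 held cells sorted for the surface receptor c-KIT, which spermatogonia gain when they begin to differentiate, and 1 held dissociated cells of an adult wild-type testis. CBX2 is a chromobox subunit of canonical Polycomb repressive complex 1 (PRC1), a complex that keeps developmental genes silent. The 4 iKO libraries came from mice with floxed Cbx2 on both alleles and a Cre recombinase that tamoxifen activates, expressed from the Rosa26 locus. These mice were given 3 injections of 150 µL of tamoxifen at 20 mg/mL in corn oil. Among the 4 control libraries, replicates 1 to 3 carried the floxed alleles without Cre and had the same injections, while replicate 4 carried Cre and 1 floxed allele and had a mock injection of corn oil. Replicates 1 and 2 of both groups, called the first set here, were sorted to 300 to 600 cells/µL, and replicates 3 and 4, the second set, to 1000 cells/µL. Nothing in the labels says that the replicates were separate animals, so p-values measure only the spread between these libraries, which may be technical. A further 8 samples of Cbx2 amplicons were not analysed here.

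The c-KIT libraries held between 40143602 and 55132158 UMIs each, and 17857 cells were kept, from 1436 in iKO replicate 1 to 3080 in control replicate 3. Median UMIs per kept cell lay between 8819 in control replicate 2 and 14113 in iKO replicate 4. Barcodes called as cells took 53.2% to 57.5% of all UMIs in the first set and 78.7% to 83.6% in the second, so the first set held more RNA outside cells. The adult library held 63672243 UMIs and 2360 kept cells, with a median of 4872.5 UMIs. Germ cells of the sorted libraries were placed in undifferentiated spermatogonia-like, differentiating spermatogonia-like, early meiotic-like and spermatid-like classes by marker genes. Unnamed clusters carried markers of 2 classes at once, had no leading gene or, for 1 cluster of 696 cells led by Plk1, Cenpa and Ccnb1, were led by more markers of another class than of differentiating spermatogonia. Leydig-like cells (62) and macrophage-like cells (40) were set aside. Unnamed clusters, 1 of them with Sertoli markers, were counted as germ cells.

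Cbx2 RNA was lower in every iKO library than in every control library, which checks the labels of the knockout. Cbx2 (ENSMUSG00000025577) lies on chromosome 11 at 119022962 to 119031270 of GRCm38, on the plus strand. Over all kept cells it stood at 31.6, 28.6, 35.02 and 30.6 CPM in control replicates 1 to 4 and at 19.5, 20.0, 24.2 and 22.3 CPM in iKO replicates 1 to 4. The means were 31.4 ± 2.69 and 21.5 ± 2.17 CPM (SD, n = 4 each), a log2 difference of -0.55 (exact permutation p = 0.0286, two-sided, the smallest that 70 assignments can give). edgeR over all genes gave an adjusted p of 1, and of 0.0905 with the replicate number as a block. The deletion removes exon 3 (119024175 to 119024240) and exon 4 (119026450 to 119026555), and the mutant transcript joins exon 2 to exon 5. RNA of a deleted allele may therefore still be counted, which was not measured here, so these counts do not measure how many cells lost the gene.

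Differentiating spermatogonia-like cells showed the tightest Cbx2 values, at 47.1, 43.2, 46.2 and 44.3 CPM in control replicates 1 to 4 and 29.6, 30.6, 31.6 and 32.3 CPM in iKO replicates 1 to 4. The means were 45.2 ± 1.77 and 31.1 ± 1.21 CPM (SD, n = 4 each; exact permutation p = 0.0286), so the iKO libraries kept 68.7% of the control level. The log2 difference was -0.54 (SE 0.0616), with an edgeR adjusted p of 0.117 that became 8.52e-06 with the replicate block. Undifferentiated spermatogonia-like cells held 54.3 ± 8.10 CPM in controls and 38.1 ± 8.20 CPM in iKO libraries (SD, n = 4 each; exact permutation p = 0.0571). Early meiotic-like cells held less Cbx2 RNA in both groups, 10.6 ± 4.49 and 9.04 ± 4.99 CPM (SD, n = 4 each; exact permutation p = 0.629). These means rest on 9 to 16 Cbx2 UMIs in each library of the first set, and without control replicate 1 the control mean, 8.34 CPM, was below the iKO mean. The log2 difference in early meiotic cells was -0.40 (SE 0.378), or -0.60 with the block, and ran from -0.68 without iKO replicate 2 to -0.13 without iKO replicate 3. Over all germ cells the means were 31.6 ± 2.57 and 21.6 ± 2.12 CPM, with an edgeR adjusted p of 1 and of 0.0447 with the block. The blocked call was lost with predicted doublets kept, and without both libraries numbered 2, 3 or 4. The Cbx2 difference did not itself differ between differentiating and undifferentiated cells (0.06 on the log2 scale, edgeR adjusted p = 1), nor between differentiating and early meiotic cells (0.01, adjusted p = 1), by a class by group term.

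**Figure D1:**
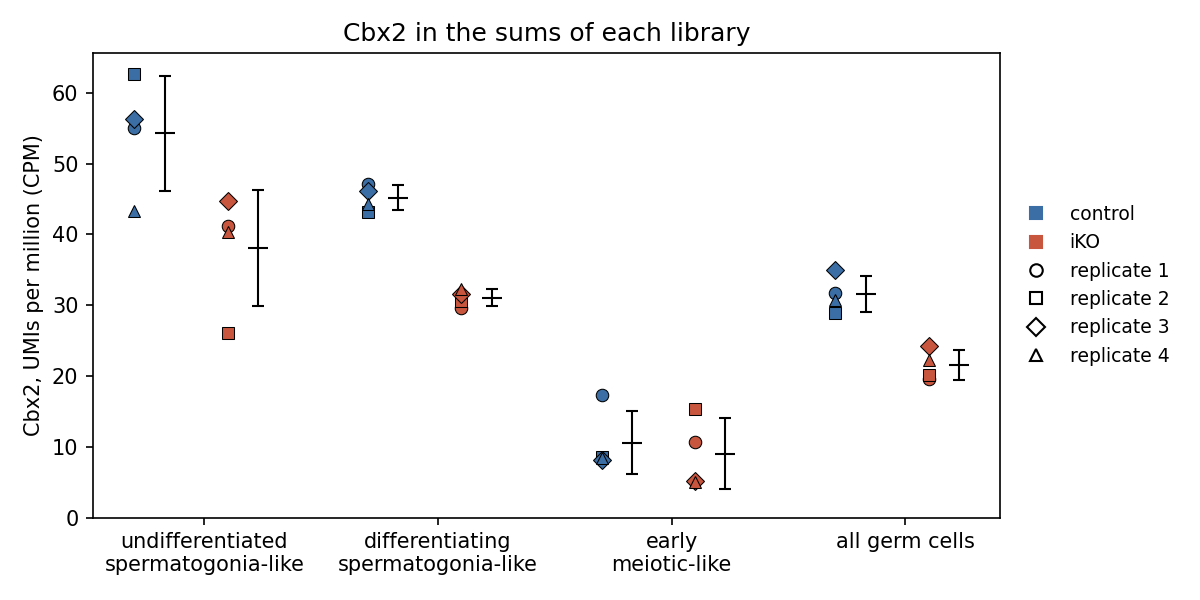
Cbx2 in CPM of UMIs (linear axis from 0) in the summed cells of each c-KIT library, by germ cell class, with blue points for control and red points for iKO libraries, marker shapes for replicates, and black bars for the mean ± SD. In differentiating cells the 4 iKO libraries sit between 29.6 and 32.3 CPM and the 4 controls between 43.2 and 47.1 CPM.

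A Cbx2 UMI was seen in 46.3% of 3995 control and 35.4% of 3312 iKO differentiating cells, whose median depths were 14932 and 15014 UMIs. Spermatid-like cells of the same libraries, taken as background for this gene, showed a UMI in 2.95% of 576 control and 1.55% of 579 iKO cells at 4782.5 and 4361 UMIs. Among undifferentiated cells the shares were 64.7% of 329 control cells and 54.5% of 308 iKO cells. Early meiotic cells gave 7.17% of 2763 and 5.12% of 2304 cells, at median depths of 8171 and 8324 UMIs.

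The first question in the series design is whether the deletion alters which cell types are present, and no class share differed by more than the spread between libraries. Shares of the iKO libraries count all cells, whether or not they had lost the gene. Differentiating cells made up 40.8% ± 7.74 of control and 39.0% ± 8.21 of iKO germ cells (SD, n = 4 each; exact permutation p = 0.743), a difference of -1.82 points. They were lower in the iKO library of all 4 same-numbered pairs (exact paired p = 0.125, the smallest that 16 sign flips can give). Undifferentiated cells made up 3.58% ± 0.573 and 3.62% ± 1.37 (SD, n = 4 each; exact permutation p = 0.971). Early meiotic cells made up 24.8% ± 21.4 and 25.2% ± 21.4, spermatid-like cells 7.83% ± 8.52 and 8.05% ± 9.53, and unnamed clusters 23.0% ± 19.2 and 24.2% ± 20.6. Every class had an adjusted permutation p of 0.971.

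Shares depended on the set more than on the genotype, and the sort concentration and the RNA outside cells differed between the sets. Spermatid-like and unnamed cells stood mostly in the first set and early meiotic cells in the second. Within the first set the iKO minus control differences were -2.05 points for differentiating, -1.42 for undifferentiated, 0.423 for early meiotic, 0.387 for spermatid-like and 2.66 for unnamed cells. Within the second set they were -1.59, 1.503, 0.253, 0.0558 and -0.218 points in the same order. Among differentiating cells, a cluster led by Gm26917 and Nutm1 stood almost entirely in the first set, and clusters led by linker histone genes, by Plk1 and Ube2c, and by Nutm1 with E2f2 mostly in the second, while the other differentiating clusters were found in both. Early meiotic clusters led by Stra8, the retinoic acid target that opens meiosis, and by Rad51ap2 also stood mostly in the second set. Barcodes above the mitochondrial limit, which were left out, made up 4.15 points more of the called barcodes in iKO libraries (higher in 4 of 4 pairs; exact permutation p = 0.486, exact paired p = 0.125).

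**Figure D2:**
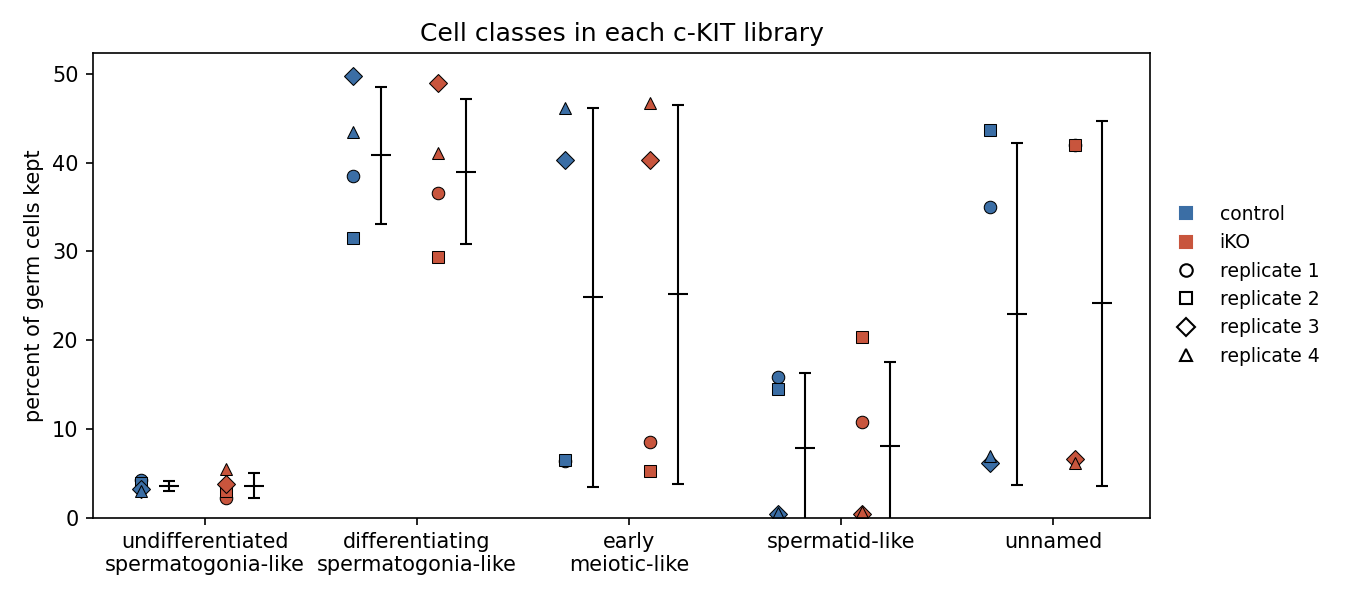
Percent of kept germ cells in each class (linear axis from 0, where error bars reaching below 0 end), with blue points for control and red points for iKO libraries, marker shapes for replicates, and black bars for the mean ± SD. Differentiating cells average 40.8% in controls and 39.0% in iKO libraries, and the 2 sets lie far apart in early meiotic, spermatid-like and unnamed cells.

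The series design next asks how gene expression changes once Cbx2 is deleted. The sums hold all iKO cells, and how many had lost the gene was not measured here, so cells that kept it may dilute a change. In differentiating spermatogonia, the cells the sort was made for, no single gene passed edgeR without the block. The gene with the lowest p after Cbx2 was Gt(ROSA)26Sor, the noncoding RNA at the locus that carries Cre, at 32.2 ± 9.60 CPM in controls and 18.0 ± 1.64 CPM in iKO libraries (log2 difference -0.83, SE 0.212). Of the G2/M and mitosis list 20 of 23 members were higher, by a median log2 difference of 0.05, although no single member passed. The camera test of this list gave an adjusted p of 0.0464, and an adjusted p = 0.785 with an estimated correlation. It passed with the block too (adjusted p = 5.67e-04) but was lost without control replicate 1 (adjusted p = 0.481), control replicate 2 (0.691), iKO replicate 3 (0.425) or iKO replicate 4 (0.262). The mitotic kinesin Kif20a stood at 112 ± 8.21 and 120.5 ± 5.21 CPM and the spindle protein Hmmr at 54.0 ± 4.33 and 57.7 ± 3.44 CPM in control and iKO libraries. The lists of Polycomb genes, Hox genes and developmental regulators did not pass the camera test, while of their members Cbx8, a chromobox subunit, was among the 17 genes edgeR called with the block without both libraries numbered 4.

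By edgeR, 0 of 13404 genes passed an adjusted p of 0.05 in differentiating cells. At an unadjusted p under 0.05 there were 139, where chance alone would give about 670.2. The fit without the block was therefore conservative, and its 0 is little evidence that expression was unchanged. DESeq2 called 1 gene, Cbx2, with 63 unadjusted. With the replicate number as a block edgeR called 10 genes, 5 higher and 5 lower, and with the set as a covariate it called Cbx2 and CAAA01147332.1. Fitted within 1 set, 0 genes were called in the first set (341 unadjusted) and 92 in the second set, of which 86 were lower in iKO libraries. Without control replicate 4 the count over both sets was 1, Gt(ROSA)26Sor. Apart from Cbx2, the blocked calls, given with the log2 difference of the blocked fit, were lower Gt(ROSA)26Sor (adjusted p = 5.24e-04) and higher Meioc, a regulator that keeps germ cells in the meiotic programme (0.22, adjusted p = 0.0216). They also held Prss50, a testis protease (0.24, adjusted p = 0.0239), Ankrd26 (0.25, adjusted p = 0.0239), mt-Atp8 (0.24, adjusted p = 0.00392) and CAAA01147332.1 (0.87, adjusted p = 1.9e-05), all higher. Ankrd26 lies within 10 Mb of Gt(ROSA)26Sor, the 1 of 94 tested genes there that the blocked fit called, and its log2 ratio was 0.0991 in pair 4, whose control carries Cre, against 0.265 to 0.374 in the others. Lower in iKO libraries were Hist1h2ak (-0.56, adjusted p = 0.0134), Rps27rt (-0.46, adjusted p = 0.0195) and Rpl36al (-0.21, adjusted p = 0.0243). These blocked genes other than Cbx2 and Gt(ROSA)26Sor were chosen after their values were seen. Of the 10, only Cbx2, Gt(ROSA)26Sor and CAAA01147332.1 were called in every blocked fit that left out both libraries of a number. Meioc was lost without both numbered 2 or both numbered 3, with the stricter cell filter and with centred genes. Histone and ribosomal protein genes have near-identical copies, so counts of single members are uncertain.

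Genes with the smallest p in differentiating cells are given as values, since none passed. Higher in iKO libraries were Zfp68 (46.2 ± 2.05 against 52.1 ± 1.82 CPM), Stk17b (43.4 ± 1.42 against 48.7 ± 2.35 CPM), Parl, a rhomboid protease of mitochondria (18.3 ± 2.32 against 22.9 ± 1.42 CPM), Atad2b and Armc7. Lower were Arhgap10 (71.8 ± 2.02 against 63.7 ± 2.02 CPM), the glycolytic enzyme Aldoc (36.3 ± 1.79 against 31.4 ± 1.23 CPM) and the sterol carrier Stard4 (41.6 ± 1.63 against 37.0 ± 0.587 CPM). Among canonical PRC1 members, 10 of 13 were higher and 3 lower (camera adjusted p = 0.328), with Cbx8 at 55.3 ± 9.27 and 64.4 ± 7.43 CPM (log2 difference 0.21). Variant PRC1 members were 5 higher and 10 lower of 15 (adjusted p = 0.376), with Wdr5 at 215 ± 3.67 and 206 ± 4.39 CPM and Bcorl1 at 20.6 ± 2.59 and 18.7 ± 1.57 CPM. PRC2 members, which place the mark that chromobox proteins read, split 6 against 6 (adjusted p = 0.855), with Jarid2 at 116 ± 7.01 and 110.2 ± 3.86 CPM. Hox genes were 3 higher and 5 lower of 8 (adjusted p = 0.852), all near the detection limit, with Hoxb9 at 1.67 ± 0.423 and 1.21 ± 0.252 CPM. Developmental regulators often bound by Polycomb were 8 higher and 5 lower of 13 (adjusted p = 0.852), with Gata2 at 8.09 ± 1.04 and 7.57 ± 1.09 CPM and Nkx2-5 at 1.11 ± 0.147 and 1.46 ± 0.178 CPM.

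Germ cell stage marker lists did not pass the camera test in differentiating cells. The same lists named the clusters, here and in the other classes, so cells with shifted markers could fall into another class. The test therefore cannot show that stages were unchanged. Differentiating markers split 6 against 6 (camera adjusted p = 0.852), with Stra8 at 203 ± 23.7 and 184.5 ± 23.1 CPM and the transcription factor Dmrt1 at 336 ± 23.5 and 325 ± 17.7 CPM. Undifferentiated markers were 4 higher and 3 lower (adjusted p = 0.845), preleptotene markers 9 and 2 (0.362), leptotene markers 8 and 6 (0.328), pachytene markers 8 and 6 (0.852), round spermatid markers 6 and 5 (0.931) and elongating spermatid markers 9 and 3 (0.852). For the undifferentiated and elongating lists the median difference was above 0 while the test pointed down. Sertoli cell markers were higher for 9 of 10 members (adjusted p = 0.190), and this passed with the block at an adjusted p of 1.25e-07, or an adjusted p = 0.646 with an estimated correlation. Leydig markers were 0 higher and 3 lower and endothelial markers 1 and 2 (adjusted p = 0.328 each). Cyclin-dependent kinase inhibitors were 4 higher and 2 lower (0.855), p53 targets 10 and 8 (0.743), retinoic acid pathway genes 6 and 10 (0.328), and G1/S and replication genes 9 and 15 (0.852). DNA methylation genes were 3 higher and 7 lower (0.855), interferon response genes 3 and 2 (0.852), and apoptosis genes 4 and 9 (0.328). KIT signalling genes were 4 higher and 6 lower (0.852). The piRNA pathway, which silences transposons in germ cells, was 4 higher and 12 lower (adjusted p = 0.200), with Tdrd1 at 60.9 ± 2.14 and 56.1 ± 4.36 CPM. Immediate early and heat shock genes were 12 higher and 3 lower (0.562), mitochondrially encoded genes 5 and 8 (0.855), and cytosolic ribosomal protein genes 37 and 45 (0.743).

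Undifferentiated spermatogonia, the stage before the sorted one, showed 1 gene past the threshold, a fall of Gt(ROSA)26Sor from 50.5 ± 12.9 to 23.8 ± 1.85 CPM. Its log2 difference was -1.12 (SE 0.177, edgeR adjusted p = 0.0155, lower than the control mean in 4 of 4 iKO libraries), and the blocked adjusted p was 2.98e-05. Of the cell cycle lists, 21 of 23 G2/M members were higher (camera adjusted p = 4.19e-04, or an adjusted p = 0.853 with an estimated correlation), and 18 of 24 G1/S and replication members (adjusted p = 0.0203, or an adjusted p = 0.694 with an estimated correlation). Of the mitochondrially encoded genes 11 of 13 were lower (adjusted p = 0.00826, or an adjusted p = 0.853 with an estimated correlation). No member of these lists passed over all genes without the block, and 1, mt-Nd3, passed when adjusted over the list alone. The mitotic cyclin Ccnb1 stood at 187 ± 7.93 and 216 ± 31.3 CPM, the replication helicase subunit Mcm5 at 166 ± 10.9 and 186 ± 10.97 CPM, and mt-Nd3, a subunit of respiratory complex I, at 160.2 ± 41.5 and 106 ± 19.1 CPM.

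Markers of the stem cell state gave mixed values in undifferentiated cells, with 7 of 11 higher and 4 lower (camera adjusted p = 0.347). Gfra1, the receptor for the niche factor GDNF, stood at 10.4 ± 3.79 and 15.6 ± 7.51 CPM (log2 difference 0.75, unadjusted p = 0.0130), and the transcription factor Etv5 at 5.57 ± 3.41 and 9.45 ± 5.22 CPM (0.79, unadjusted p = 0.0452). Kit itself stood at 252.5 ± 12.5 and 228 ± 19.8 CPM. Smallest unadjusted p among genes higher in iKO libraries belonged to Echs1, a fatty acid oxidation enzyme (21.6 ± 1.48 against 33.1 ± 3.85 CPM), Lcmt1 (70.04 ± 5.33 against 91.6 ± 5.76 CPM), Samhd1, Kpna2 and Cd9. Lower were Iqce (28.5 ± 1.91 against 18.1 ± 3.49 CPM), the tight junction gene Ocln (10.0 ± 0.699 against 3.87 ± 2.67 CPM) and Prpf4. Canonical PRC1 members were 6 higher and 7 lower (adjusted p = 0.711), variant PRC1 members 8 and 7 (0.933), PRC2 members 4 and 7 (0.573), Hox genes 4 and 2 (0.792) and developmental regulators 4 and 4 (0.933). Pcgf2 stood at 45.5 ± 9.69 and 38.4 ± 5.66 CPM and Eed at 149 ± 12.4 and 135 ± 5.12 CPM.

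edgeR called 1 of 10340 genes in undifferentiated cells with 270 at an unadjusted p under 0.05, where chance alone would give about 517. DESeq2 called 1, and the block called 2, adding lower mt-Nd3 (adjusted p = 7.01e-05). The log2 ratios of mt-Nd3 in pairs 1 to 4 were -0.405, 0.101, -1.08 and -0.851, so the fall was mostly of the second set. In differentiating cells they were 0.0413, -0.0415, -0.624 and -0.624. There its iKO difference itself differed between the sets in edgeR with the block (-0.629, adjusted p = 6.71e-05). Gt(ROSA)26Sor missed the threshold without control replicate 1 (edgeR adjusted p = 0.148), 2 (0.0555) or 3 (0.215) or iKO replicate 3 (0.144) or 4 (0.214), with log2 differences between -1.14 and -1.02. Without control replicate 2 the 1 gene called was mt-Nd3. Within the first set 1 gene was called, higher Tmsb4x, and within the second set 39 genes, all lower. With the block 2 more lists passed, elongating spermatid markers, lower for 6 of 6 (adjusted p = 1.6e-09, or an adjusted p = 0.169 with an estimated correlation), and ribosomal protein genes, lower for 56 of 82 (adjusted p = 0.00699, or an adjusted p = 0.931 with an estimated correlation). The G2/M call was lost without iKO replicate 3 (adjusted p = 0.160). The G1/S call was lost without control replicate 4 (0.123) or iKO replicate 1 (0.0622), 2 (0.0782) or 4 (0.0613). The mitochondrial call was lost without control replicate 1 (0.0973) or 3 (0.0860) or iKO replicate 3 (0.385) or 4 (0.0613).

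Early meiotic cells, which follow the sorted stage, showed no gene and no list past the threshold without the block. edgeR called 0 of 11435 genes, with 28 at an unadjusted p under 0.05, and DESeq2 called 0, with 18 unadjusted. Since chance alone would give about 571.8 genes at that level in edgeR, its fit was conservative here. The 0 is little evidence that expression was unchanged. Gt(ROSA)26Sor stood at 82.0 ± 18.3 CPM in controls and 49.6 ± 14.3 CPM in iKO libraries, and the mitotic ubiquitin ligase partner Ube2c at 42.0 ± 2.76 and 55.0 ± 9.56 CPM. Higher values were also seen for Morc4 (14.2 ± 4.02 against 24.8 ± 5.35 CPM), Apba3, Mllt1, Avpi1 and Acer2, and lower values for the microtubule regulator Clasp2 (83.8 ± 6.87 against 67.3 ± 6.34 CPM), the zinc transporter Slc39a1, Rpl36al and Akap17b. Canonical PRC1 members were 6 higher and 7 lower (camera adjusted p = 0.891), with Cbx8 at 23.2 ± 8.91 and 33.4 ± 5.75 CPM. Variant PRC1 members were 4 higher and 11 lower (0.791), PRC2 members 2 and 9 (0.623), and the lowest adjusted p of any of 25 lists was 0.623, or 0.970 with an estimated correlation. Markers of leptotene split 7 against 7 (0.891), with Spo11, which makes the breaks that start recombination, at 60.2 ± 14.7 and 65.6 ± 17.4 CPM.

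With the replicate block edgeR called 20 genes in early meiotic cells, 2 higher and 18 lower, and within the second set alone 7, all lower, against 0 in the first set (192 unadjusted). Among the 20 were mt-Nd3 (145 ± 32.3 against 108 ± 24.7 CPM, blocked adjusted p = 2.22e-06), Gt(ROSA)26Sor (blocked adjusted p = 0.00639) and Rpl36al (0.0248). The others named here, with log2 differences of the blocked fit, were chosen after their values were seen: Hist1h2ba, a testis histone variant (-0.41, blocked adjusted p = 0.00137), Hist1h2ak (-0.68, 2.46e-04), Hist1h4d (-0.49, 8.74e-04) and the linker histone Hist1h1c (-0.31, 0.0103). Without both libraries numbered 1 the blocked count was 91, and without both numbered 3 or both numbered 4 it was 3 and 2.

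Summed over all germ cells, leptotene and zygotene markers were higher for 13 of 14 members (camera adjusted p = 0.00161), and endothelial markers lower for 4 of 4 (adjusted p = 0.0142). With an estimated correlation the lists had an adjusted p = 0.944 and an adjusted p = 0.943. These sums hold the unnamed clusters too, 1 of which carried Sertoli markers, and mix changes within a class with changes in class shares. Rad51ap2, a recombination protein, stood at 46.7 ± 13.9 and 55.9 ± 10.1 CPM, Meioc at 205 ± 28.1 and 221 ± 10.5 CPM, and the endothelial receptor Tie1 at 1.62 ± 0.116 and 1.31 ± 0.0901 CPM. The leptotene call was lost without control replicate 1 (adjusted p = 0.970, with the median difference at -0.00278), control replicate 2 (0.148) or iKO replicate 4 (0.736). The endothelial call was lost without control replicate 1 (0.247) or 2 (0.220) or iKO replicate 3 (0.125) or 4 (0.116). With the block 3 more lists passed: preleptotene markers, higher for 11 of 11 (adjusted p = 0.00795), elongating spermatid markers, higher for 10 of 12 (0.0109), and Sertoli markers, higher for 9 of 11 (1.59e-06). With an estimated correlation the first and last had an adjusted p = 0.8285 and the elongating list an adjusted p = 0.891.

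By edgeR, 0 of 16782 genes passed over all germ cells, and DESeq2 and the blocked fit each called Cbx2 alone. Without the block 66 genes had an unadjusted p under 0.05, where chance alone would give about 839.1. That fit was therefore conservative too. Within either set 0 genes were called (558 unadjusted in the first and 572 in the second). Undifferentiated markers were 9 higher and 4 lower (camera adjusted p = 0.0568), with Etv5 at 2.14 ± 0.320 and 2.83 ± 0.331 CPM. Peritubular and stromal markers split 3 against 3 (0.622), macrophage markers were 2 higher and 1 lower (0.991), and lymphocyte markers 4 higher of 4 (0.439). Canonical PRC1 members were 8 higher and 5 lower and PRC2 members 5 and 7 (0.991 each), variant PRC1 members 6 and 9 (0.273), Hox genes 7 and 7 (0.958) and developmental regulators 12 and 17 (0.991). Cbx6 stood at 2.98 ± 0.458 and 2.40 ± 0.303 CPM. The smallest unadjusted p values belonged to Egr2, Spin4, Plekha5, Adam8 and Abhd17b among higher genes and to Gt(ROSA)26Sor, Fer1l4, Cnn1 and Arhgap10 among lower ones, with Plekha5 at 48.4 ± 1.28 and 52.9 ± 1.62 CPM.

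**Figure D3:**
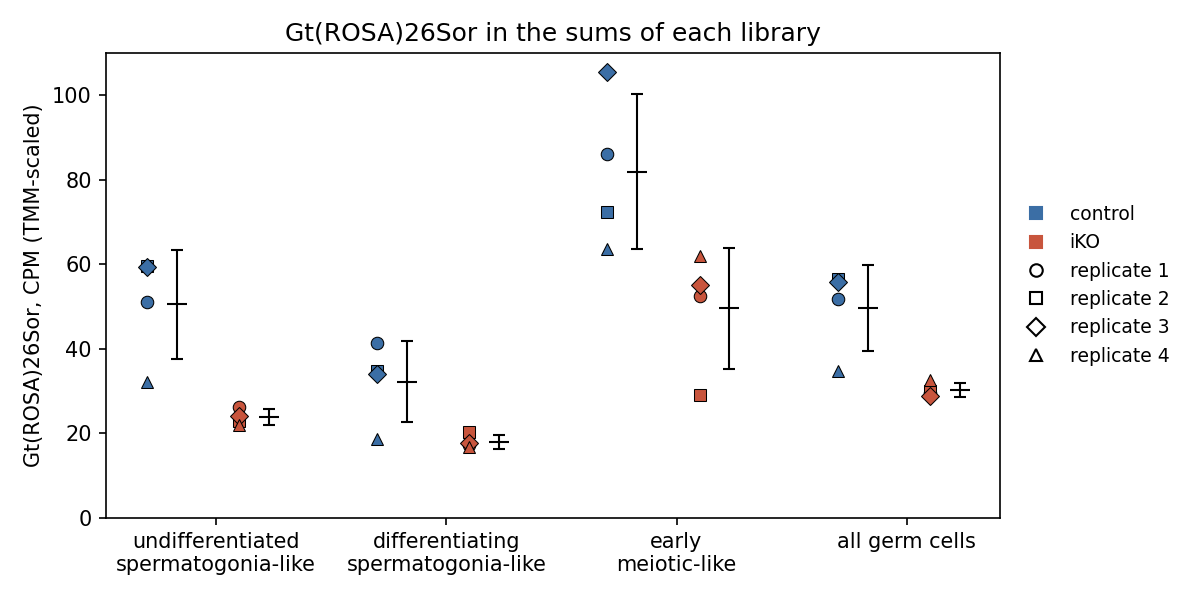
Gt(ROSA)26Sor in TMM-scaled CPM (linear axis from 0) in the summed cells of each c-KIT library, by germ cell class, with blue points for control and red points for iKO libraries, marker shapes for replicates, and black bars for the mean ± SD. In differentiating cells control replicate 4, the control that carries Cre, stands at 18.6 CPM beside an iKO mean of 18.0 CPM, while control replicates 1 to 3 average 36.7 CPM.

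Gt(ROSA)26Sor (ENSMUSG00000086429), annotated as an antisense gene on chromosome 6 at 113067428 to 113077333 of GRCm38, minus strand, stood below every other control in the control that carries Cre, and nearer the iKO mean than theirs. In differentiating cells it stood at 36.7 ± 3.99 CPM in control replicates 1 to 3 (SD, n = 3), 18.6 CPM in control replicate 4 and 18.0 ± 1.64 CPM in the iKO libraries (SD, n = 4). In undifferentiated cells the values were 56.7 ± 4.81, 32.1 and 23.8 ± 1.85 CPM, and in early meiotic cells 88.1 ± 16.7, 63.6 and 49.6 ± 14.3 CPM, with control replicate 4 above every iKO library in both of these classes. Whether the counting separated strands is not given in the sources used here, so reads of a gene on the other strand cannot be told apart from it.

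The adult testis library answers where Cbx2 is expressed in the normal tissue, and its Cbx2 UMIs stood mostly in differentiating spermatogonia-like cells. These 92 cells held 15 Cbx2 UMIs, or 25.4 CPM (95% exact Poisson interval 14.2 to 41.9). Early meiotic-like cells held 0.864 CPM (0.178 to 2.52) from 3 UMIs, late spermatocyte-like cells 0.227 CPM from 1 UMI and spermatid-like cells 0.244 CPM (0.0502 to 0.712) from 3 UMIs. Of the 207 early meiotic-like cells, 129 lay in a cluster led by Piwil1, a pachytene marker of the fixed lists. Its median was 18907 UMIs against 3362.5 in the other cluster, so the level of the class says little of cells that enter meiosis. With the stricter cell filter differentiating cells held 42.1 CPM (15.5 to 91.7) and early meiotic cells 0, which allows up to 0.9748 CPM at 3 counts. Thinned to 2000 UMIs per cell they held 16.3 CPM (3.36 to 47.6) from 3 UMIs and 4.83 CPM (0.585 to 17.5) from 2 UMIs, intervals that overlap. A Cbx2 UMI was seen in 15.2% of the 92 differentiating cells (exact binomial interval 8.58% to 24.2%) and in 0.206% of 1454 spermatid-like cells, whose median depths were 5836 and 5365.5 UMIs. Leydig-like cells held 1 UMI, and Sertoli-like cells held 0, which allows up to 12.2 CPM at 3 counts. That limit covers all UMIs of the class, of which the free-RNA estimate reached its upper bound of 90%, so it says little of Sertoli cells. With 1 library there was no test, and intervals and limits cover counting error only.

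**Figure D4:**
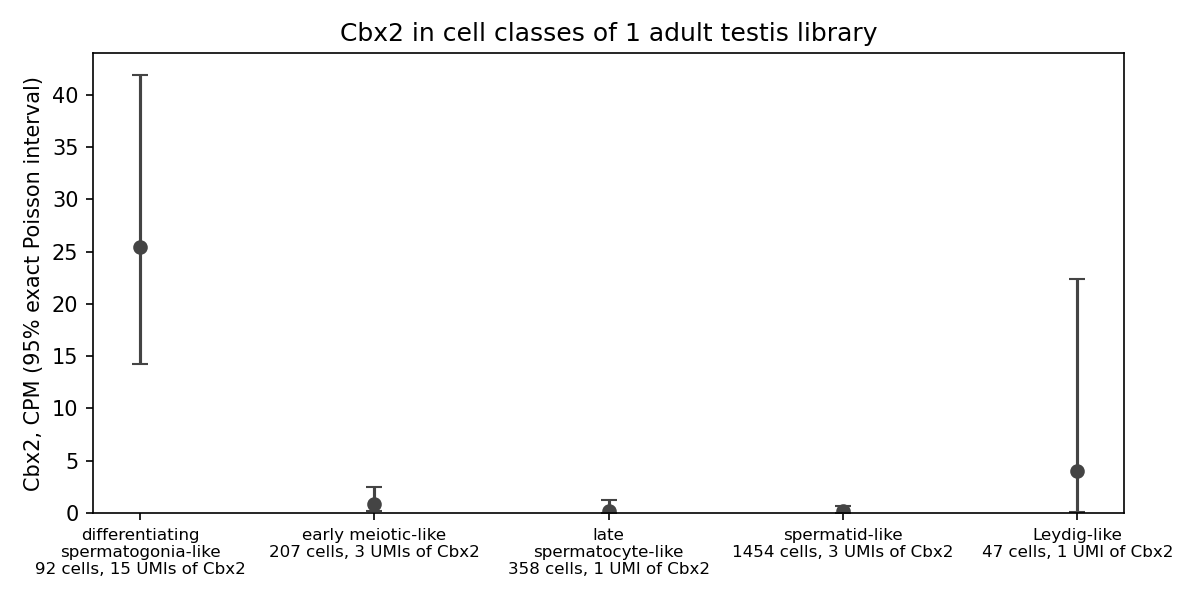
Cbx2 in CPM (linear axis from 0) in the cell classes of the adult testis library, with points for the summed cells of a class and bars for the 95% exact Poisson interval. The differentiating spermatogonia-like class stands at 25.4 CPM and early meiotic-like, late spermatocyte-like and spermatid-like cells at 0.864 CPM or less, while the interval of the Leydig-like class rests on 1 UMI.

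Other Polycomb genes followed different courses through the adult germ cell classes. The variant PRC1 subunit Pcgf6 stood at 11.9 CPM (4.76 to 24.4) in differentiating cells and 166 CPM (153 to 180.2) in early meiotic cells, and the methyltransferase Ezh2 at 99.9 CPM (76.0 to 129) and 216 CPM (201 to 232). Yaf2 was lower in early meiotic cells, at 144 CPM (115 to 178) against 25.6 CPM (20.6 to 31.5), or 48.3 CPM when thinned. Adult and sorted levels come from different kits (3' and 5') and unlike early meiotic cells. Of the 207 adult cells of that class, 129 were in a cluster led by Piwil1, a pachytene marker of the fixed lists, with Tex101 and Sycp1. Its median was 18907 UMIs, against 3362.5 in the other cluster. Pcgf5 stood at 252 CPM (213 to 296) and 259 CPM (242 to 276) in the adult classes and was lower in early meiotic cells of the sorted controls. The PRC2 subunit Suz12 stood at 96.5 CPM (73.1 to 125) and 29.9 CPM (24.5 to 36.3) in the adult classes but was higher in early meiotic cells of the sorted controls, 193.3 ± 14.0 against 235.8 ± 14.4 CPM (SD, n = 4; edgeR adjusted p = 0.00826). Cbx8 stood at 37.2 CPM (23.3 to 56.4) in differentiating cells, with 0 UMIs in early meiotic and spermatid-like cells. Bmi1, at 62.6 CPM (44.1 to 86.3) in differentiating cells, was still at 51.2 CPM (47.3 to 55.4) in spermatid-like cells. Scml2, Auts2 and Rbbp7 were among the genes the adult cells were clustered on, so their levels between classes are not given as results. Spermatid-like cells made up 61.6% of the 2360 kept cells (exact binomial interval 59.6% to 63.6%), late spermatocyte-like cells 15.2% (13.7% to 16.7%) and early meiotic-like cells 8.77% (7.66% to 9.99%). Differentiating spermatogonia-like cells made up 3.90% (3.15% to 4.76%), Leydig-like cells 1.99%, Sertoli-like cells 1.74% and unnamed clusters 6.82%. Undifferentiated spermatogonia formed no class of their own here. In the differentiating class 1 cluster of 15 cells, with Ccnd2 and Uchl1 among its leading genes, scored 2.027 on undifferentiated and 2.105 on differentiating markers. The class may therefore hold undifferentiated cells, and its Cbx2 level cannot be given to differentiating cells alone.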

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

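The tests of Gt(ROSA)26Sor, the splits of the samples and the tests of a difference between the protocol sets were chosen only after the results were seen, and those of short transcripts, S phase, Cbx2 RNA, free RNA and mixtures of cells were written before.

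Gt(ROSA)26Sor RNA was lower in iKO libraries in every class, and the control that carries Cre was lower than the other controls. In differentiating cells control replicate 4 stood at 50.79% of the mean of control replicates 1 to 3, nearer the iKO mean than theirs, and the same held in undifferentiated cells (56.6%) and early meiotic cells (72.3%), as the Cre allele at the locus needs. Tamoxifen is argued against, since the iKO mean was 48.98% of the controls that had the same injections, each of which stood above every iKO library in these classes. Loss of Cbx2 RNA stays open, because the evidence rests on 1 library and differs between classes: TMM-scaled Cbx2 of control replicate 4 stood at 46.28 CPM in differentiating cells (41.7 to 47.82 in the other controls) but at 44.71 CPM in undifferentiated cells, below the others (54.76 to 62.12). A candidate explanation is that the inserted Cre allele lowers RNA of the locus, and effects of Cre on other genes cannot be separated from those of the Cbx2 deletion in a comparison with control replicates 1 to 3, which lack Cre.

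In iKO replicates 3 and 4, but not 1 and 2, 86 genes of differentiating cells were called lower, among them 19 ribosomal protein and 4 histone genes. Their median transcript length was 522.25 nt against 889 nt in 10000 expression-matched random lists, the lowest percentile (0), so a loss of short transcripts from these libraries may be part of the cause, but all 374 short transcripts had median log2 ratios of only -0.0343 and -0.0461 in pairs 3 and 4 (long ones 0.00376 and 0.000956), against -0.299 and -0.231 for the 86 genes, which were chosen on these pairs, so most of the size stays open. Lower Cbx2 RNA is argued against as the whole cause, since in pairs 1 and 2, which took no part in choosing the genes and where Cbx2 was as low, their median log2 ratios were 0.138 and -0.0282 (mean 0.0549). Fewer cells in S phase cannot be told apart: the G1/S list averaged -0.0313 in pairs 3 and 4, the direction set beforehand, but the size it would have had to reach was added after the values were seen. By a set by group term with the block, 50 genes in differentiating cells, 45 of them among the 86, and 39 in undifferentiated cells differed between the sets, while edgeR without the block called 0, with 503 and 637 at an unadjusted p under 0.05 and 62 of the 86 among the first.

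Differentiating cells of the iKO libraries kept 68.7% of the control level of Cbx2 RNA, and 3 explanations were tested. Free RNA is argued against, since spermatid-like cells of the same libraries held 1.795 CPM, or 5.73% of the level in differentiating cells. A mixture of cells without any Cbx2 RNA and cells at the control level is argued against, since the excess of cells with no Cbx2 UMI was 12.18% of what it predicts. An even lowering in every cell may account for the values, with an excess of 0.4482 points (SE 0.774 over 4 pairs, above 0 in 1 of 4, the first at 2.75). A deleted allele may still give RNA that is counted, so neither pattern says which cells lost the gene.

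Of 200 groups of 4 libraries, 9 held a library far from the others, where chance gives about 5%. Cbx2 in early meiotic cells stood at 17.32 CPM in control replicate 1 and between 8.11 and 8.53 CPM in the other controls. In differentiating cells mt-Nd3 stood at 128.7 CPM in iKO replicate 1 against 88.9 to 92.7 CPM, and in undifferentiated cells at 98.16 CPM in control replicate 2 against 176 to 186 CPM. Lcmt1 stood at 77.95 CPM in control replicate 3 (others 66.3 to 68.2 CPM) and Gfra1 at 16.05 CPM in control replicate 4 (others 8.13 to 8.70 CPM) in undifferentiated cells. Cenpe in early meiotic cells stood at 99.13 CPM in control replicate 2 (others 70.6 to 73.4 CPM). Over all germ cells Plekha5 stood at 50.29 CPM in control replicate 4 (others 47.6 to 47.9 CPM), Rad51ap2 at 70.99 CPM in iKO replicate 4 (others 50.4 to 51.4 CPM) and Tie1 at 1.445 CPM in iKO replicate 3 (others 1.26 to 1.29 CPM). The iKO minus control share of undifferentiated cells was 2.927 points higher in the second set than in the first (exact permutation p = 0.0556, the smallest that 36 assignments can give), and every pair of the first set moved the opposite way from every pair of the second.

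Over the 35 splits of the 8 libraries into 4 and 4, chance could not be excluded for any count above 0. For genes, 9 splits gave as many as the real 1 in undifferentiated cells (highest other 358). For lists, 31 splits gave as many as 1 in differentiating (highest other 8), 14 as many as 3 in undifferentiated (7) and 33 as many as 2 over all germ cells (13). Every one of the 35 splits reaches a real count of 0, so the splits say nothing of chance for edgeR genes in differentiating (highest other 4240), early meiotic (4769) and all germ cells (8999) or for lists in early meiotic cells (8). The split by protocol set gave the highest count of genes in each class, which points to a structure of the samples. Of the 8 splits that part all 4 pairs, too few for a share under 0.05, edgeR without the block called 1 gene in undifferentiated cells for the real split and none for the others. Among these splits the blocked fit called 10, 2, 20 and 1 genes for the real split in these classes and at most 82, 21, 29 and 0 for the others.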

How the results depend on the processing

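Each protocol set alone, the block with pairs left out or with another cell filter, the set covariate without control replicate 4 or for lists, calling cells by order of magnitude, and other class limits or denominators were chosen only after the data were seen. Named genes were mostly chosen by their p in the main fit of these libraries, which the alternatives fit again, so keeping a direction was near given. Of 2451 values of named genes under alternatives, 2449 kept their direction. The exceptions were Hoxb9 in differentiating cells, 0.0229 with the stricter cell filter and the block, and mt-Nd6 in undifferentiated cells, 0.0045 with the stricter filter. The cause was not tested for these or the changes that follow, except that fewer libraries enter where some are left out. The replicate block changed the count of genes to 10 in differentiating, 2 in undifferentiated, 20 in early meiotic and 1 in all germ cells, and made Cbx2 pass in differentiating (-0.54) and all germ cells (-0.55). It changed no other call of Cbx2 or of a class share. With the block and doublets kept the counts were 10, 2 and 23 in the first 3 classes and 0 in all germ cells (edgeR, 629 unadjusted), with the stricter filter 11, 4, 15 and 1 in all 4 classes (undifferentiated cells without iKO replicate 1, which had 14 cells left), and with centred genes 13, 2, 4 and 1. With the block and both libraries of a number left out, from 1 to 4, they were 107, 6, 7 and 17 in differentiating, 5, 3, 2 and 2 in undifferentiated, 91, 19, 3 and 2 in early meiotic cells, and over all germ cells 1 without number 1 (Cbx2), 0 without number 2 or 3 (406 and 580 unadjusted) and 1 without number 4, which was Gt(ROSA)26Sor and not Cbx2. With the set as covariate 2, 2 and 2 genes were called in the first 3 classes and 0 in all germ cells (edgeR, 350 unadjusted), and without control replicate 4 as well 4, 2, 1 and 3. The second set alone gave 92, 39 and 7. DESeq2 called 1 gene in differentiating and 1 in all germ cells, and no low-count filter gave 14 in undifferentiated cells. Leaving out 1 library gave 0 to 1 genes in differentiating and undifferentiated cells and 0 in the others. For lists, the block and the set covariate gave 2 in differentiating and 5 in undifferentiated cells, the block 5 over all germ cells, and the estimated correlation 0 in each. Leaving out 1 library gave 1 to 6 lists in differentiating, 1 to 5 in undifferentiated, 0 to 2 in early meiotic and 2 to 8 in all germ cells, where the leptotene median ran from -0.00278 to 0.257. The difference in undifferentiated share reversed to -1.42 points in the first set, -0.0543 with centred genes, -0.0422 with order-of-magnitude calling and -0.476 with named classes as denominator. That of spermatid-like cells reversed to -0.0247 with the stricter filter and -0.434 with order-of-magnitude calling, and that of unnamed cells to -0.218 in the second set and -0.591 with the mixed cluster counted as early meiotic. Leaving out 1 library moved the differences from -0.566 to 0.497 points for undifferentiated, -5.15 to 1.38 for differentiating, -6.84 to 7.44 for early meiotic, -3.88 to 2.90 for spermatid-like and -4.73 to 8.13 for unnamed cells. In the adult library the stricter filter gave 1.34% differentiating, 7.34% early meiotic, 10.5% late spermatocyte-like, 72.3% spermatid-like, 1.05% Sertoli-like and 0.991% Leydig-like cells. Order-of-magnitude calling gave 14.6% early meiotic, 9.002% late spermatocyte-like, 66.9% spermatid-like, 0.973% Sertoli-like, 1.34% Leydig-like and 3.77% unnamed cells. Adult Cbx2 stood at 42.1 CPM in differentiating cells with the stricter filter, and in early meiotic cells at 0 CPM with that filter or order-of-magnitude calling and 4.83 CPM when thinned. At 15 Cbx2 UMIs in its differentiating cells, the depth of the adult library limits what can be said of classes with fewer.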

Other observations

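The comparisons of classes within the control libraries and of histone genes were chosen only after the data were seen.

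Polycomb genes differed between successive germ cell classes of the control libraries, as most tested genes did, and whether they did so more often than other genes was not tested. From undifferentiated to differentiating cells 15 of 40 were higher and 15 lower, where edgeR with the library as a block called 8259 of 12313 genes. Pcgf6, which defines a variant PRC1, fell from 74.2 ± 8.44 to 9.15 ± 2.15 CPM (log2 difference -3.10, adjusted p = 1.48e-18, lower in 4 of 4 libraries), and the CpG-binding subunit Kdm2b from 103 ± 12.6 to 46.3 ± 1.95 CPM. Cbx7 fell from 13.5 ± 2.86 to 4.83 ± 0.540 CPM, while the ubiquitin ligase subunit Ring1 rose from 9.48 ± 2.82 to 33.6 ± 3.35 CPM. Cbx2 itself stood at 53.3 ± 7 and 46.3 ± 2.45 CPM (adjusted p = 0.0715, higher in 1 of 4 libraries).

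From differentiating to early meiotic cells, where 9571 of 13280 genes were called, 13 of 41 Polycomb genes were higher and 16 lower (12 and 17 with RLE scaling, where 3 changed sign; 15 and 17 without control replicate 2). Cbx2 fell from 43.3 ± 3.70 to 11.02 ± 4.27 CPM (log2 difference -2.18, adjusted p = 8.15e-07, lower in 4 of 4 libraries), with Cbx8 (53.04 ± 10.3 to 24.4 ± 9.62 CPM) and Phc2 (73.0 ± 1.39 to 30.2 ± 5.71 CPM). Scmh1 rose from 32.5 ± 1.63 to 119 ± 28.3 CPM, Phc1 from 42.4 ± 1.70 to 108 ± 13.6 CPM, Rnf2 from 44.7 ± 8.95 to 102 ± 5.58 CPM and Pcgf6 from 8.49 ± 1.71 to 50.2 ± 8.36 CPM. In iKO libraries 15 were higher and 14 lower at the first step and 12 and 16 at the second.

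Histone genes were lower in iKO libraries for 31 of 38 members in differentiating cells (camera p = 1.25e-07, p = 0.123 with an estimated correlation) and 30 of 31 in early meiotic cells (p = 4.45e-04, p = 0.393 with an estimated correlation). Their median log2 ratios in pairs 1 to 4 were 0.0961, -0.129, -0.107 and -0.432 in differentiating and -0.20, 0.375, -0.364 and -0.415 in early meiotic cells, so 1 pair in each class went the other way. Of the 86 genes lower in iKO replicates 3 and 4, whose transcripts were short, 4 were histone genes.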
